A study of Mus musculus with 20 samples.

How the data were processed

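RNA was measured in adipocyte precursor cells sorted by flow cytometry from 2 fat depots of female C57Bl6/J mice aged 8 to 11 weeks. VWAT is the perigonadal visceral depot and SWAT the inguinal subcutaneous depot. Per the labels' protocols, the gate took cells without the leukocyte marker CD45 and the endothelial marker CD31 that carried CD29, CD34 and Sca1, with or without CD24. Mice ate a standard diet (SD, day 0) or a high-fat diet with 60% lard (HFD) for 3 days. Each library was made from cells pooled from 3 mice, and each of the 4 groups has 5 libraries, so a replicate is a separate pool of mice. Nothing in the labels says that VWAT and SWAT libraries of the same number come from the same mice. Libraries were made from polyadenylated RNA with a stranded (dUTP) kit and read as 75 bp single reads, per the labels' protocols.

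The authors deposited a table of read counts per gene, as whole numbers that were not normalized. Reads were aligned with TopHat to the mm9 mouse genome and counted with HTSeq, per the submitters' processing notes, which give no versions. The strand setting of the counting and the gene annotation are not given in the sources used here. Counts of genes that overlap another gene on the opposite strand, or that have near-identical copies, are therefore uncertain. The table has 33929 rows. Of these, 5 are HTSeq summary rows, which hold 27.0% of all reads on average (21.8% to 37.0% per library) and were left out of library sizes and tests. Another 25 rows carry calendar-date serial numbers in place of gene symbols, as a spreadsheet makes from symbols such as those of the septin and March families. They hold 0.0837% to 0.180% of reads, name no gene and were left out, which leaves 33899 genes. The rows do not say which gene each one was. Every library column was used.

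Reads counted on genes numbered 14.4 to 47.5 M (mega-reads) per library (mean 28.8 M ± 10.5, SD, n = 20). Replicates were compared before averaging. Over 40 pairs of libraries of the same group, the chi-square statistic of their counts divided by its degrees of freedom was 19.2 to 420, so no pair agreed within sampling noise, as copies of the same library would. That each library is 1 replicate follows from the labels. In the shallowest library 1 CPM (counts-per-million) stands for about 14.4 reads. Genes of that level carry counting error on top of the spread between pools.

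Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept with edgeR's expression filter by group, libraries were scaled by TMM, and 1 negative binomial model with a mean per group was fitted to all 20 libraries, so that the groups share an estimate of the spread. edgeR's quasi-likelihood test (robust) gave a p per gene, adjusted by Benjamini-Hochberg with a threshold of 0.05. In what follows, "edgeR adjusted p" stands for this value. Standard errors (SE) of log2 fold changes are the fold change divided by the square root of the test's F. The comparisons were HFD against SD within VWAT, HFD against SD within SWAT, the difference between these (the diet by depot interaction), and VWAT against SWAT on each diet. Fold changes of the depots were also set against each other across genes.

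Lists of genes were fixed before the data were examined, 32 in all. They cover estrogen response, DNA replication and G1/S, mitosis and G2/M, adipogenic transcription factors, mature adipocyte, de novo lipogenesis, cholesterol synthesis and uptake, liver X receptor targets, fatty acid oxidation and PPAR targets, oxidative phosphorylation, glycolysis, extracellular matrix, inflammatory cytokines and NF-kB targets, interferon response, immediate early and dissociation response, circadian clock, endoplasmic reticulum stress, glucocorticoid targets, DPP4+ interstitial progenitor, committed preadipocyte, CD142+ stromal regulator, visceral developmental, subcutaneous developmental, leukocyte, endothelial, mesothelial, mural, mammary and skin epithelial, ovary and reproductive tract, skeletal muscle, Schwann and erythroid genes. None was chosen from these libraries. Several lists share genes. Each list was tested with limma's camera (limma 3.58.1), which compares a list's genes with all others, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 32 lists. Camera with an estimated correlation and fry were run beside it. List tests between the depots on HFD were added after seeing the data.

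Genes named in the text follow a rule written before the data were examined. It takes the 8 higher and 8 lower genes of largest fold change past the threshold, with an average log2 CPM of at least 1 and at least 4 of 5 libraries beyond the other group's mean, leaving out predicted and clone genes. To these it adds the 3 members of smallest p of each list described, and the estrogen receptors, Pgr, Greb1, Mki67, Pparg, Pdgfra, Pdgfrb, Dlk1 and the genes of the sort markers. Other genes named are members of these lists. For VWAT against SWAT on SD the first part of the rule was applied to the model of 18 libraries described next.

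Some choices were made after seeing the data. The libraries labelled VWAT SD 5 and SWAT SD 5 carry the other depot's marker genes, so each result was also computed from 18 libraries, without these. Fold changes between diets followed the GC content of transcripts, so each result was also computed with an offset per gene and library equal to the library's median deviation in 20 bins of GC content. GC content and length came from GENCODE annotation of the GRCm38 build, matched by symbol. That is not the authors' build, so it was used for these properties alone and no coordinates are given. A GC content was found for 98.6% of the tested genes. The share of reads assigned to no feature was also tried as a covariate, and a comparison was made of the 14 of the 18 libraries in which it is under 6%.

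Alternatives planned beforehand were DESeq2's size factors, upper quartile scaling, DESeq2 1.42.0's Wald test, limma-voom with sample weights, no filter, a stricter filter (1 CPM in 10 libraries), the replicate number as a block, only the 10 libraries compared, a log2 fold change of at least 1, and leaving out each library in turn. The closing section gives their effect. On data simulated from the real means and library sizes, with 100 genes changed by a log2 fold of 1 and 100 by 2, the test of diet in VWAT with 20 libraries recovered 41% and 96% of them with 3 false calls (14032 genes). With 18 libraries the shares were 47% and 100% in VWAT (14139 genes), 53% and 99% in SWAT (14086 genes), and 38% and 98% between depots on SD (14083 genes). False calls among all calls were 10 of 157, 10 of 162 and 5 of 141 in the same order. Genes were drawn independently in these simulations, without a GC trend, misplaced libraries or other structure among samples. The shares therefore hold for data without such structure. In a simulation with an added GC trend over 14152 genes, the GC correction lowered false calls from 2086 to 13 and recovered 199 of 200 changed genes. Measures of single libraries were compared with exact two-sided permutation tests over 252 splits, adjusted over the 14 tests of that family.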

Results

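RNA was sequenced from adipocyte precursor cells of the visceral (VWAT) and subcutaneous (SWAT) fat of female mice on a standard diet (SD) or after 3 days of a high-fat diet (HFD). The 4 groups hold 5 libraries each, and each library is a pool of 3 mice. Reads counted on genes (M, mega-reads) averaged 22.6 M ± 11.7 in VWAT SD, 31.3 M ± 5.99 in VWAT HFD, 29.9 M ± 10.9 in SWAT SD and 31.5 M ± 12.8 in SWAT HFD (SD, n = 5). The comparisons ask what the first days of an obesogenic diet change in these precursors in each depot, and how the depots differ on each diet.

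Genes of the sort markers were measured in every group. Among markers that the gate selects, Cd34 averaged 1775 ± 108 counts-per-million (CPM) in VWAT SD, 1903 ± 192 in VWAT HFD, 1794 ± 67.7 in SWAT SD and 2125 ± 247 in SWAT HFD. Ly6a, which encodes Sca1, averaged 1460, 1053, 1965 and 2092 CPM in the same order, and Itgb1 (CD29) averaged 328, 706, 291 and 541 CPM (HFD against SD, edgeR adjusted p = 0.00509 in VWAT and 0.0642 in SWAT). Cd24a (CD24), with which the gate took cells or without, averaged 5.47, 4.25, 10.47 and 14.1 CPM. Among markers that the gate excludes, Ptprc, which encodes CD45, averaged 1.38, 0.658, 1.26 and 0.83 CPM, while Pecam1 (CD31) averaged 31.3, 26.2, 26.4 and 20.9 CPM. Cdh5, another endothelial gene, averaged 23.2, 21.9, 19.1 and 16.7 CPM.

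The libraries also differed in technical measures. Spearman's correlation, across genes, of a gene's deviation in a library with its GC content averaged 0.325 in VWAT SD, -0.479 in VWAT HFD, 0.296 in SWAT SD and -0.397 in SWAT HFD (exact two-sided permutation p = 0.0238 in VWAT and 0.0159 in SWAT; 0.0556 and 0.0444 adjusted over 14 tests; n = 5 per group). VWAT SD 1, at -0.54, lay with the HFD libraries, and SWAT HFD 2 was at 0.05. The share of reads assigned to no feature averaged 6.60% ± 2.81 in VWAT SD, 4.11% ± 0.381 in VWAT HFD, 5.48% ± 2.47 in SWAT SD and 3.75% ± 0.534 in SWAT HFD (exact two-sided permutation p = 0.119 in VWAT and 0.0714 in SWAT; 0.139 and 0.111 adjusted). It was 9.06% in VWAT SD 2, 9.80% in VWAT SD 3 and 9.80% in SWAT SD 4. Diet results are therefore given from all 20 libraries and beside them with a GC correction chosen after seeing the data. The libraries labelled VWAT SD 5 and SWAT SD 5 carried the marker genes of the other depot, so values from the other 18 libraries are given as well.

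**Figure D1:**
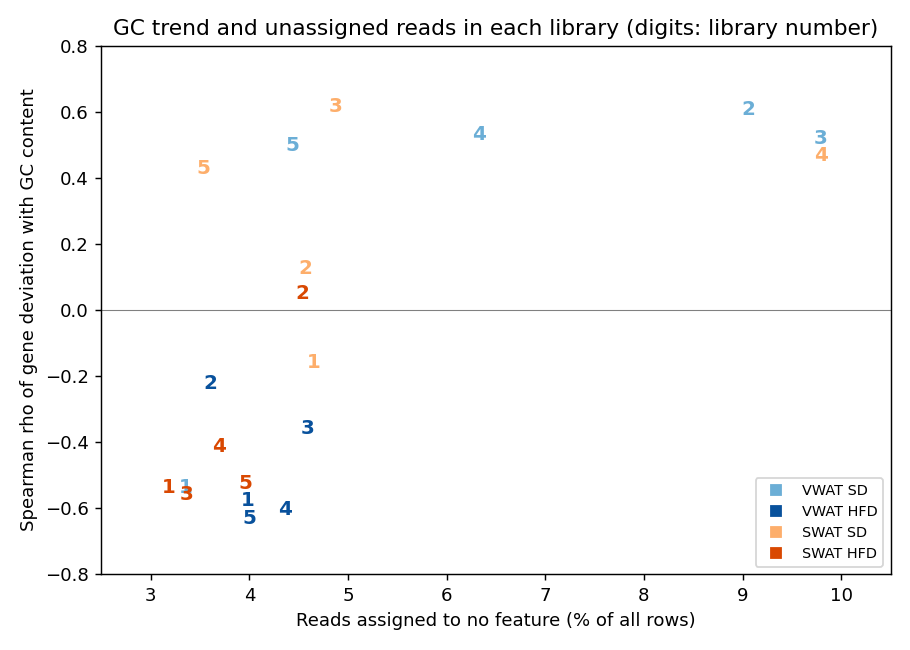
Correlation of gene deviation with GC content (Spearman's rho across genes) against the share of reads assigned to no feature (percent) in each of the 20 libraries, by group, with digits for library numbers. VWAT SD 1 lies at -0.54 with the HFD libraries, and VWAT SD 2, VWAT SD 3 and SWAT SD 4 have the highest shares.

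In visceral precursors, genes of cell division, extracellular matrix and inflammatory signalling were higher after 3 days of HFD. By camera 6 lists were called, and 0 with an estimated correlation. The inflammatory median of 0.86 was 0.29 with 18 libraries and the GC correction. There 5 of 100 splits of the libraries, the real grouping among them, reached it. The GC trend of the libraries moved with diet, and their share of unassigned reads could not be told apart from diet. Mki67, a marker of cycling cells, rose by a log2 fold change of 3.12 ± 0.75 (SE; edgeR adjusted p = 0.00505), from 2.15 ± 2.95 CPM on SD to 19.8 ± 11.5 CPM on HFD (SD, n = 5). Top2a, the DNA topoisomerase of dividing cells, rose by 3.45 ± 0.85 (edgeR adjusted p = 0.00585). Col3a1, a fibrillar collagen, averaged 8249 ± 5645 CPM on SD and 24940 ± 4303 on HFD. Of 14242 tested genes, 2803 were higher and 3699 lower on HFD at an edgeR adjusted p under 0.05, 3171 of them by at least 1 on the log2 scale.

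All 32 measured mitosis genes rose in VWAT (32 adjusted over the list alone), with a median log2 fold change of 2.75. Examples are Prc1, a cytokinesis protein, at 3.01 ± 0.58 and the ubiquitin-conjugating enzyme Ube2c at 2.92 ± 0.53 (edgeR adjusted p = 0.00311 and 0.00309), and the cyclin Ccna2 at 3.07. The camera adjusted p was 2.2e-14, and the adjusted p was 0.865 with an estimated correlation. With 18 libraries and the GC correction 25 of the mitosis genes rose, with a median of 2.18. Of 34 DNA replication genes 15 rose and 1 fell (20 and 1 adjusted over the list alone; camera adjusted p = 5.76e-04, and adjusted p = 0.865 with an estimated correlation). They include the polymerase subunit Pole at 1.83 ± 0.38 and the origin factor Mcm10 at 2.35 ± 0.53. Their median was 0.83, and 0.60 with 18 libraries and the GC correction, where 10 rose and 1 fell (12 and 1 adjusted over the list alone).

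Of 47 extracellular matrix genes 23 rose and 2 fell (24 and 2 adjusted over the list alone), with a camera adjusted p of 1.37e-06 and an adjusted p of 0.381 with an estimated correlation. Timp1, an inhibitor of matrix metalloproteinases, rose by 1.58 ± 0.21 (edgeR adjusted p = 9.86e-04), from 64.9 ± 20.4 to 195 ± 21 CPM (SD, n = 5), and the collagens Col6a3 and Col12a1 rose by 1.02 ± 0.18 and 2.02 ± 0.35. With 18 libraries and the GC correction 29 matrix genes rose and 0 fell. Of 26 inflammatory genes 14 rose and 1 fell (16 and 2 adjusted over the list alone; camera adjusted p = 6.95e-05, and adjusted p = 0.865 with an estimated correlation). The chemokine Cxcl10 rose by 1.56 ± 0.22 and the interleukin-1 receptor Il1r1 by 1.43 ± 0.27. Only 4 of the 26 rose with 18 libraries and the GC correction, where Cxcl10 was at 0.99 and Il1r1 at 0.60. Of 14 committed preadipocyte genes 7 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 0.0278, and adjusted p = 0.865 with an estimated correlation). With 18 libraries and the GC correction 3 of them rose and 0 fell (4 and 0 adjusted over the list alone). Lipoprotein lipase, Lpl, rose by 1.40 ± 0.25 and was at 0.49 with 18 libraries and the GC correction (edgeR adjusted p = 0.138).

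Leukocyte genes were lower in VWAT on HFD, with 6 of 23 lower, 0 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0457, and adjusted p = 0.865 with an estimated correlation). The complement genes C1qa and C1qb of macrophages fell by 1.84 ± 0.57 and 1.57 ± 0.48 on the log2 scale. With 18 libraries and the GC correction 1 leukocyte gene was lower.

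Single genes of lipid storage and adipogenic control fell, while their lists, with members going both ways, were not called. Srebf1, which switches on lipogenic genes, fell by 1.28 ± 0.26 and Cebpa, an adipogenic transcription factor, by 1.47 ± 0.32 (edgeR adjusted p = 0.00311 and 0.00353), and with 18 libraries and the GC correction they were at -0.11 and -0.44 (edgeR adjusted p = 0.579 and 0.112). The lipid droplet protein Plin4 fell by 2.49 ± 0.62 and was at -1.62 with 18 libraries and the GC correction. Of the adipogenic transcription factors 1 of 19 rose and 7 fell, of mature adipocyte genes 4 of 17 rose and 8 fell, and of lipogenesis genes 3 of 15 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.540, 0.500 and 0.436). Pparg, the main adipogenic factor, was at 0.06 (edgeR adjusted p = 0.855).

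Estrogen response genes moved both ways in VWAT, 8 of 47 rising and 18 falling (8 and 20 adjusted over the list alone; camera adjusted p = 0.540). Their median was -0.51, and -0.01 with 18 libraries, where 7 rose and 13 fell (7 and 13 adjusted over the list alone). With the GC correction as well it was 0.14, where 2 rose and 2 fell (2 and 1 adjusted over the list alone). The estrogen receptor Esr1 rose by 1.00 ± 0.28 (edgeR adjusted p = 0.00924), from 60.6 ± 28.5 to 121 ± 25.1 CPM (SD, n = 5), and was at 0.36 with 18 libraries and the GC correction (edgeR adjusted p = 0.152). Greb1, an estrogen receptor target, was at 1.36 ± 0.55 with an edgeR adjusted p of 0.0491, which became 0.0936 with 18 libraries and 0.0626 with the GC correction as well. Its adjusted p was 0.0821 without VWAT SD 1, 0.101 without VWAT SD 2, 0.0971 without VWAT SD 3, 0.0934 without VWAT SD 5, 0.0512 without SWAT SD 5, 0.120 without VWAT HFD 1, 0.0617 without VWAT HFD 2, 0.0577 without VWAT HFD 4, 0.0707 without VWAT HFD 5, 0.0578 without SWAT HFD 2 and 0.0508 without SWAT HFD 5. The progesterone receptor Pgr, another target, was at 1.08 ± 0.63 (edgeR adjusted p = 0.162). Esr2 had at most 2 reads in any library and was not tested.

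The precursor receptor Pdgfrb fell by 0.96 ± 0.21 and was at -0.19 with 18 libraries and the GC correction (edgeR adjusted p = 0.00388 and 0.395), and Pdgfra was at 0.41 (edgeR adjusted p = 0.130; 0.0329 without VWAT SD 1). The proteinase inhibitor A2m rose by 3.21 ± 0.86. Cyp26b1, which degrades retinoic acid, fell by 2.53 ± 0.53 and the keratin Krt36 by 2.92 ± 0.62. The epithelial keratin Krt19 was at -3.99 ± 1.08 (edgeR adjusted p = 0.00899), and at -1.39 without VWAT SD 5 (edgeR adjusted p = 0.10). Spint2 and Cited1, at -3.14 and -2.54, likewise had edgeR adjusted p values of 0.0916 and 0.0826 without VWAT SD 5. With 18 libraries 5247 genes were called, and with the GC correction as well 1996. With the share of unassigned reads as a covariate 1880 genes were called from 20 libraries and 18 from 18, and 1 gene was called in the 14 of these with under 6% unassigned, where VWAT SD 1 is the only VWAT SD library left. Of 14029 genes tested in all 3 models, 450 were higher and 784 lower on HFD in each of them.

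**Figure D2:**
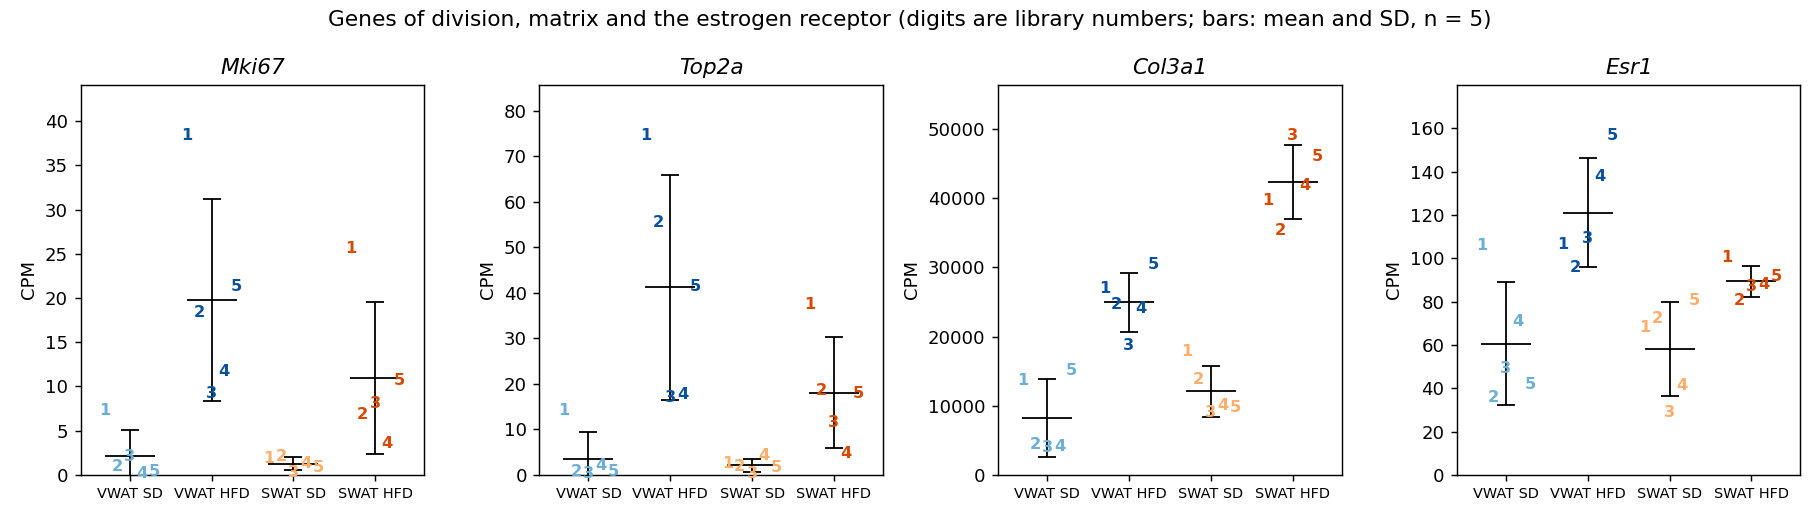
Counts-per-million (CPM) of Mki67, Top2a, Col3a1 and Esr1 in each library of the 4 groups, with digits for library numbers and bars for the mean and SD (n = 5). Mki67 averaged 2.15 in VWAT SD and 19.8 in VWAT HFD.

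In subcutaneous precursors genes of mitosis, extracellular matrix and interferon response were higher on HFD. By camera 5 lists were called, and 0 with an estimated correlation. With the share of unassigned reads as a covariate, edgeR called 0 genes. SWAT SD 4 stood apart at 9.80%, and the other SWAT SD libraries had 3.53% to 4.87% against 3.18% to 4.54% on HFD. In SWAT the share could thus be told apart from diet only in part. Ube2c rose by 2.89 ± 0.53 (SE; edgeR adjusted p = 0.0334), and Mki67 rose by 3.11 ± 0.76 (edgeR adjusted p = 0.0477), from 1.28 ± 0.727 to 10.95 ± 8.58 CPM (SD, n = 5). Col3a1 rose by 1.81 ± 0.34 (edgeR adjusted p = 0.0334), from 12090 ± 3718 to 42370 ± 5358 CPM. Among 14242 tested genes 122 were higher and 100 lower at an edgeR adjusted p under 0.05, with 4877 at an unadjusted p under 0.05 and a smallest edgeR adjusted p of 0.0334.

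Of 32 mitosis genes 18 rose in SWAT and 0 fell (31 higher adjusted over the list alone), with a median of 2.74, a camera adjusted p of 7.05e-21 and an adjusted p of 0.475 with an estimated correlation. The spindle protein Tpx2 rose by 2.60 ± 0.50 and Prc1 by 2.97 ± 0.59. Of 47 extracellular matrix genes 8 rose and 0 fell (18 higher adjusted over the list alone; camera adjusted p = 3.83e-09, and adjusted p = 0.137 with an estimated correlation). Periostin, Postn, rose by 1.92 ± 0.33, from 1094 ± 338 to 4143 ± 1087 CPM (SD, n = 5), and the collagen Col5a2 by 1.30 ± 0.23. Of 31 interferon response genes 7 rose and 0 fell (15 higher adjusted over the list alone; camera adjusted p = 4.92e-08, and adjusted p = 0.804 with an estimated correlation). The RNA sensors Ddx58 and Ifih1 rose by 1.06 ± 0.21 and 1.71 ± 0.35, and Ifi44 rose by 2.49 ± 0.57. The interferon median was 0.91 in SWAT and -0.18 in VWAT, and 0.67 in SWAT and 0.60 in VWAT with 18 libraries. With 18 libraries and the GC correction 15 mitosis, 19 matrix and 5 interferon genes rose. DNA replication genes lay higher and oxidative phosphorylation genes lower as lists (camera adjusted p = 0.0445 for both, and adjusted p = 0.804 with an estimated correlation for both), with 0 members of either list past edgeR's threshold. Their medians were 0.43 and -0.21.

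Lipid genes of SWAT moved both ways. The fatty acid carriers Fabp4 and Cd36 rose by 1.24 ± 0.26 and 1.71 ± 0.37 (edgeR adjusted p = 0.0472 for both), and neither passed with 18 libraries and the GC correction (edgeR adjusted p = 0.251 and 0.147). Cfd, which encodes adipsin, fell by 2.47 ± 0.58 and the phospholipid transfer protein Pltp, a liver X receptor target, by 1.62 ± 0.39. Cebpa and Srebf1 fell by 1.25 ± 0.31 and 1.05 ± 0.26 (edgeR adjusted p = 0.0488 and 0.0477). Cyp27a1, which makes oxysterols, fell by 1.71 ± 0.39, and the receptor phosphatase Ptpru by 1.93 ± 0.32. These falls come from all 20 libraries without the GC correction. With it 18 SWAT genes were called lower in place of 100, and 81 higher in place of 122. Committed preadipocyte genes had 2 of 14 higher (5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0550). Of 47 estrogen response genes 0 rose and 2 fell, Sult2b1 by 2.31 ± 0.57 and the complement gene C3 by 0.85 ± 0.21 (0 and 7 adjusted over the list alone; camera adjusted p = 0.305). Esr1, Pgr and Greb1 were at 0.62, 1.61 and 1.28 (edgeR adjusted p = 0.124, 0.0977 and 0.115), and Top2a was at 3.17 ± 0.86 (edgeR adjusted p = 0.0575).

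**Figure D3:**
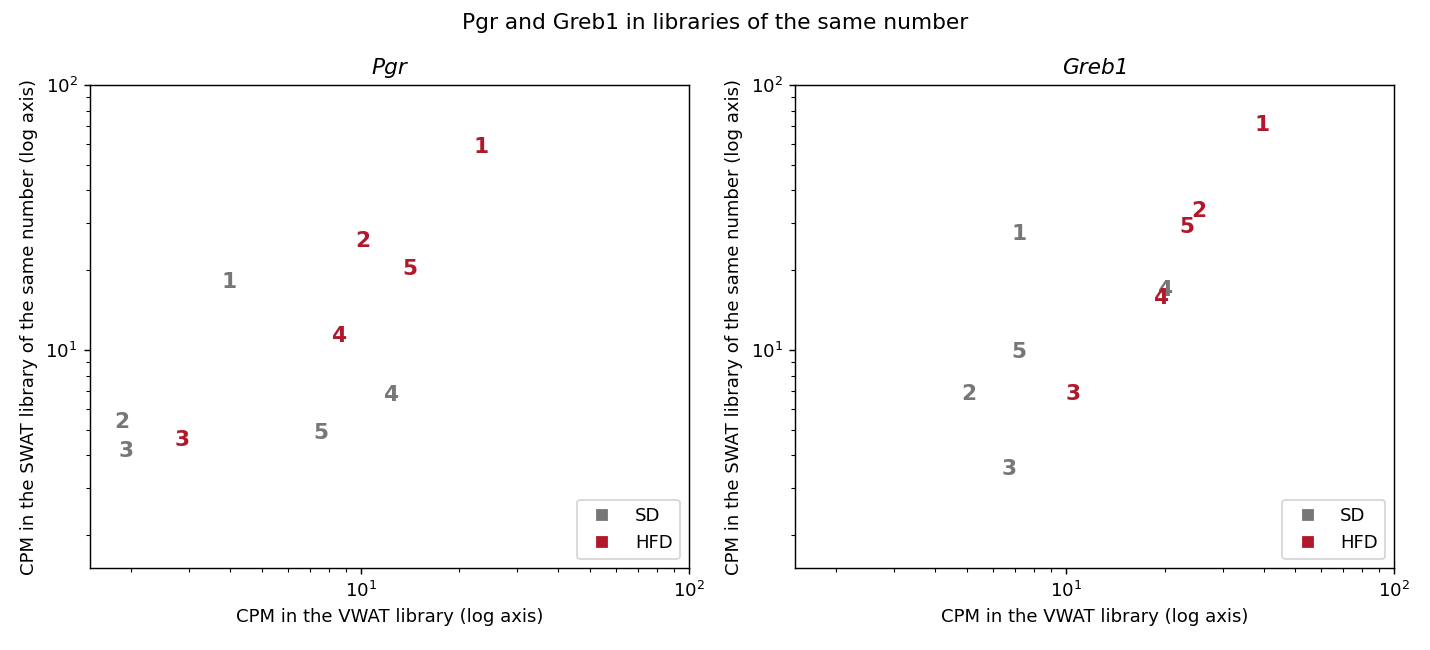
Counts-per-million (CPM) of Pgr and Greb1 in the VWAT library (horizontal axis) and the SWAT library (vertical axis) of the same number, on log axes, with SD in grey and HFD in red and digits for library numbers (all 5 numbers per diet). Pgr averaged 11.8 CPM in VWAT HFD and 24.0 in SWAT HFD.

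The SWAT count moved with single libraries. edgeR called 0 genes without SWAT SD 2, SWAT SD 3, SWAT SD 4, SWAT SD 5, VWAT HFD 2, VWAT HFD 4, SWAT HFD 1, SWAT HFD 2, SWAT HFD 3 or SWAT HFD 5, each left out alone, while with all 20 libraries DESeq2 called 2003, limma-voom 3713 and an unadjusted edgeR p under 0.05 gave 4877. It called 1 gene without VWAT HFD 5, 15 without VWAT HFD 3, 16 without VWAT SD 3, 18 without VWAT HFD 1, 28 without SWAT HFD 4, 113 without VWAT SD 4, 480 without VWAT SD 5, 2185 without SWAT SD 1 and 3362 without VWAT SD 1. With 18 libraries 92 genes were called, and 229 with the GC correction as well. In all 3 models 36 genes were higher and 15 lower. With the share of unassigned reads as a covariate edgeR called 0 genes from 20 libraries (2746 at an unadjusted p under 0.05) and 0 from 18, and it called 372 in the 14 libraries with under 6% unassigned.

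The fold changes of HFD ran alike in the depots. Across 14242 genes their Pearson correlation was 0.717 and Spearman's rho 0.795, where genes are not independent replicates. Of the genes called in both depots 104 were higher and 89 lower, 0 moved in opposite directions, and independent lists would share 24.0 and 26.0. Pearson's r was 0.281 without the expression filter, and with 18 libraries it was 0.704, or 0.111 in the 14 of these with under 6% unassigned, where VWAT SD 1 is the only VWAT SD library left. With 18 libraries and the GC correction r was 0.536, and 121 genes were higher and 38 lower in both (9.81 and 5.45 for independent lists), with 1 in opposite directions. The fold changes of either depot had a Spearman's correlation of -0.69 with GC content across genes, and the genes called higher and lower had a median GC content of 43.9% and 55.4% in VWAT and 45.9% and 56.8% in SWAT.

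**Figure D4:**
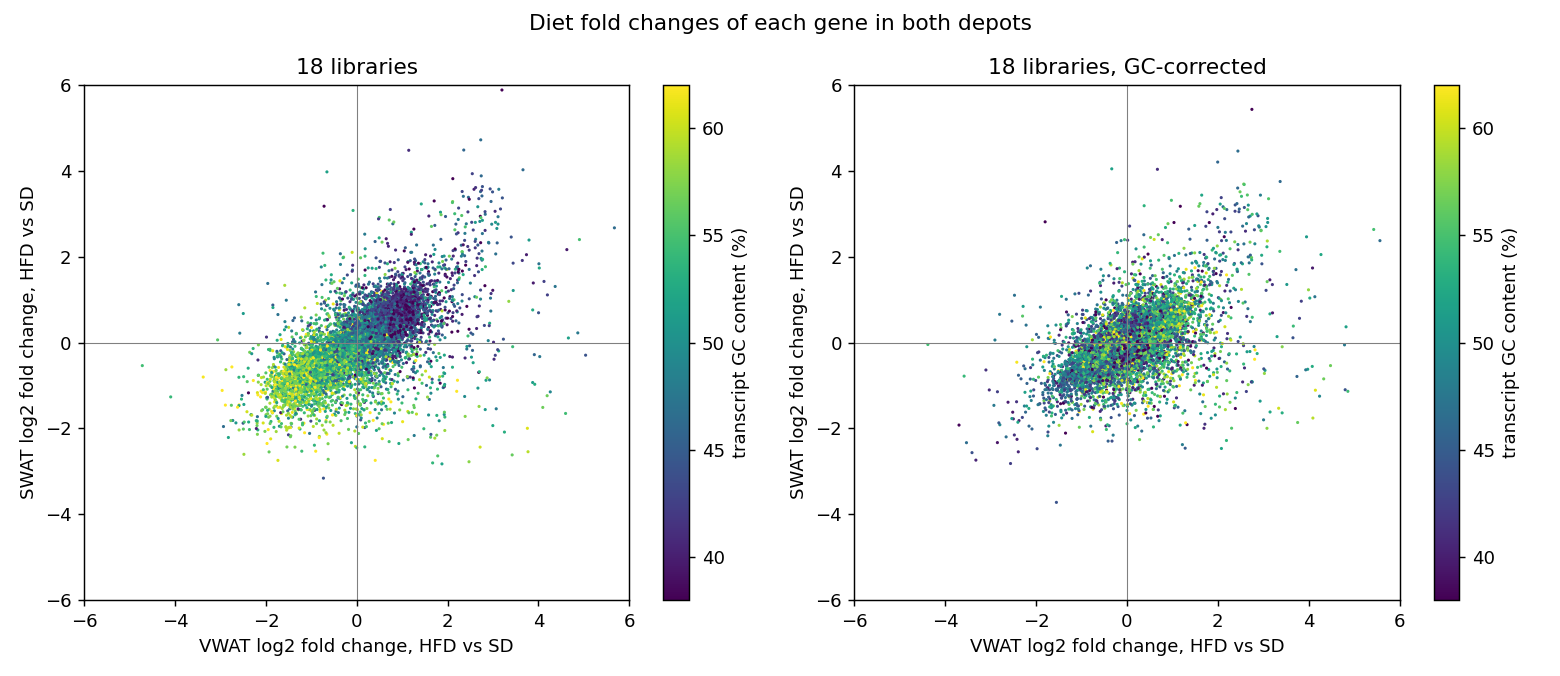
Log2 fold change of HFD against SD in VWAT (horizontal axis) and SWAT (vertical axis), with axes limited to ±6. Values come from 18 libraries, without (left) and with (right) the GC correction. Each point is a tested gene, coloured by the GC content of its transcript. Without the correction 45 genes were called higher and 35 lower in both depots, and 0 in opposite directions. With it 121 were higher, 38 lower and 1 in opposite directions.

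The diet by depot interaction, which tests whether HFD acted differently in the depots, gave 0 genes past edgeR's threshold (605 at an unadjusted p under 0.05; DESeq2 0, limma-voom 2220). With 18 libraries 1 gene passed, Frzb, which encodes a secreted Wnt antagonist. Its interaction was 3.27 ± 0.52 (edgeR adjusted p = 0.0439), and 3.28 with the GC correction. The edgeR call was lost in 14 of 18 models with 1 more library left out, and held without VWAT SD 1, SWAT SD 3, SWAT SD 4 or VWAT HFD 3. With all 20 libraries it was 5.17 ± 1.20 (edgeR adjusted p = 0.942). Frzb averaged 25.6 ± 9.01 CPM in VWAT HFD and 0.287 ± 0.101 CPM in SWAT HFD (SD, n = 5). These levels show the depot difference on HFD and not an effect of diet. The SWAT level rests on few reads, so the SWAT fold change within the interaction is a ratio near the floor. By camera 11 lists differed, 0 with an estimated correlation. The list of interferon genes had a median of -0.83 (camera adjusted p = 1.04e-11) and the inflammatory list 0.53 (camera adjusted p = 1.15e-07), with adjusted p from 0.262 to 0.785 over the 11 lists with an estimated correlation. With 18 libraries the interferon median was -0.35 (camera adjusted p = 0.00417, and adjusted p = 0.726 with an estimated correlation).

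On SD, visceral and subcutaneous precursors differed, among 18 libraries, in genes that set position in the embryo. VWAT SD 5 and SWAT SD 5 were left out for carrying the other depot's levels of such genes, so the p values on SD depend on that choice and do not allow for it. Visceral cells were higher in the mesothelial and visceral factor Wt1, by 6.71 ± 0.65 (SE; edgeR adjusted p = 5.54e-07), and in the transcription factor Tcf21, by 6.01 ± 0.53 (edgeR adjusted p = 1.49e-07). Subcutaneous cells were higher in Tbx15 and Irx1, at -7.18 ± 0.44 and -5.97 ± 0.30 (edgeR adjusted p = 6.8e-10 and 5.85e-11). These values come from 18 libraries, where Wt1 averaged 155 ± 65.1 CPM in VWAT and 1.35 ± 1.72 in SWAT (SD, n = 4) and Tbx15 averaged 0.304 and 54.4 ± 11.8. Of 14360 genes 497 were higher and 717 lower in VWAT. With all 20 libraries edgeR called 0 (1009 at an unadjusted p under 0.05; DESeq2 15, limma-voom 1318), 590 without VWAT SD 5 and 223 without SWAT SD 5.

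Of 9 visceral developmental genes 5 were higher in VWAT and 0 lower, and of 16 subcutaneous ones 7 were lower and 1 higher (1 and 9 adjusted over the list alone). Their camera adjusted p values were 7.77e-10 and 1.94e-18, and the adjusted p was 0.00436 for both with an estimated correlation. The limb factor Shox2 was at -5.93 ± 0.51 and Tbx5 at -5.16 ± 0.37. Other large differences were the relaxin family receptor Rxfp2 at 5.63 ± 0.85, renin (Ren1) at 4.85 ± 1.00 and the kinase Dapk2 at 4.56 ± 0.35 on the visceral side, and the interleukin-1 decoy receptor Il1r2 at -5.41 ± 0.28 on the subcutaneous side. Mammary and skin epithelial genes were lower in VWAT for 13 of 15 (15 adjusted over the list alone; camera adjusted p = 1.54e-25, and adjusted p = 0.0163 with an estimated correlation). Krt8, a keratin of simple epithelia, averaged 1.01 CPM in VWAT and 128 ± 93.4 in SWAT (SD, n = 4), and Epcam averaged 0.0788 and 20.5 CPM. Cldn4 was at -9.34 ± 0.90 and Krt18 at -8.34 ± 0.78. Ovary and reproductive tract genes were higher in VWAT for 4 of 7 and lower for 0 (camera adjusted p = 2.46e-04, and adjusted p = 0.00957 with an estimated correlation), among them Hoxa11 at 4.74 ± 0.59 and Star at 2.29 ± 0.37.

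Interferon response genes were lower in VWAT on SD for 15 of 31 (20 adjusted over the list alone), with a median of -0.93, a camera adjusted p of 4.74e-17 and an adjusted p of 0.0598 with an estimated correlation. Usp18, which limits interferon signalling, was at -2.43 ± 0.26, Oas2 at -2.76 and Mx1 at -4.33. Of 23 cholesterol genes 5 were lower (10 adjusted over the list alone; camera adjusted p = 6.5e-06, and adjusted p = 0.233 with an estimated correlation), with Sc4mol at -1.42 ± 0.21 and Insig1 at -1.31 ± 0.23. Estrogen response genes were higher for 2 of 47 and lower for 11 (5 and 13 adjusted over the list alone; camera adjusted p = 9.6e-04, and adjusted p = 0.0905 with an estimated correlation). This list shares Krt8 and Krt18 with the epithelial list and also holds Ltf. Krt18 averaged 0.503 CPM in VWAT and 147 in SWAT, and Ltf 0.0485 and 44.8 CPM (n = 4). The epithelial difference between depots therefore enters the estrogen list, and its share in the call was not tested. The major collagen Col1a1 was at -1.61 ± 0.20 (edgeR adjusted p = 8.79e-06), and Cd24a, which encodes the sort marker CD24, at -2.33 ± 0.48.

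**Figure D5:**
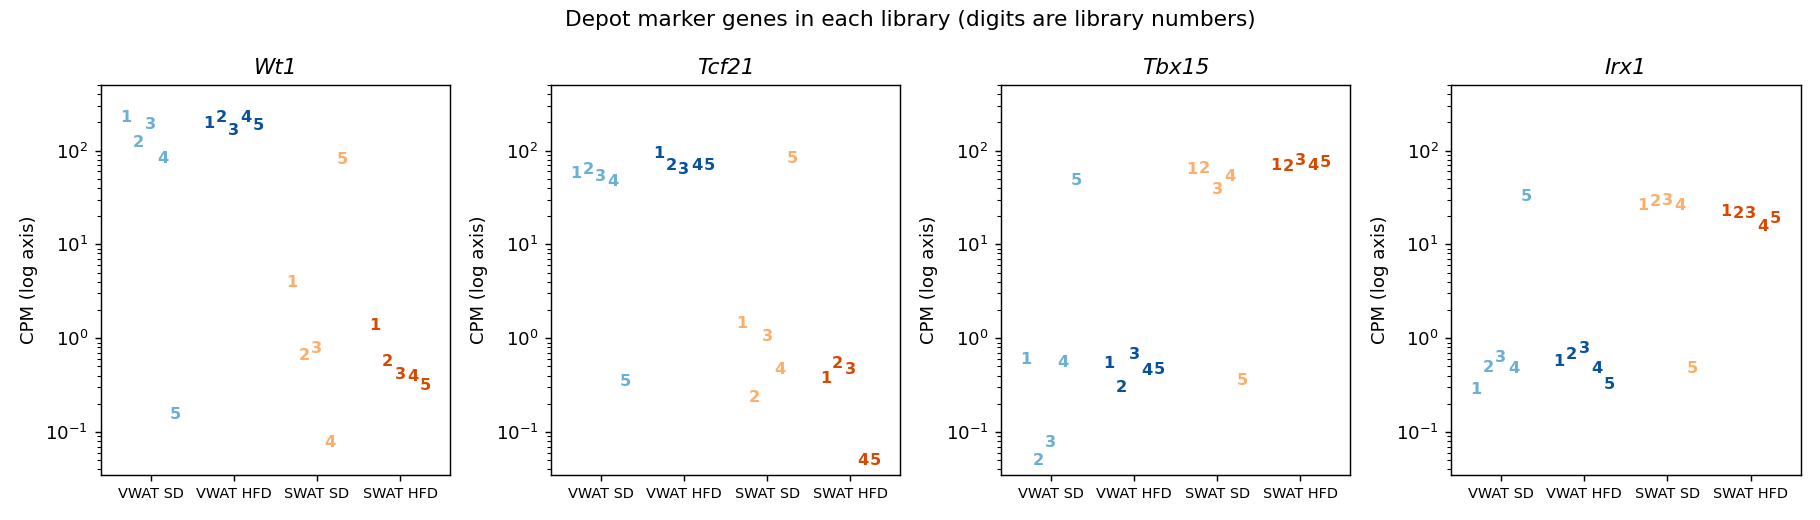
Counts-per-million (CPM) of marker genes of the depots in each library, on a log axis, with digits for library numbers and values under 0.05 drawn at 0.05. The libraries labelled VWAT SD 5 and SWAT SD 5 lie with the other depot.

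After 3 days of HFD the depots differed in developmental genes, in interferon genes, which were also lower in VWAT on SD, and in inflammatory genes. All 13 list calls on HFD were lost with an estimated correlation, those of developmental, interferon and inflammatory genes among them (adjusted p = 0.127 for interferon and 0.380 for inflammatory genes). The interferon call on SD was lost too. With 18 libraries 12 lists were called on HFD, and 5 with an estimated correlation. Wt1 was higher in VWAT by 8.29 ± 1.66 and Tcf21 by 7.98 ± 1.66 (SE, n = 5; edgeR adjusted p = 0.00837 and 0.00984), while Tbx15 was at -7.20 ± 1.53 (edgeR adjusted p = 0.0108). Wt1 averaged 198 ± 26.5 CPM in VWAT HFD and 0.606 ± 0.427 in SWAT HFD (SD, n = 5). Frzb was higher in VWAT by 6.48 ± 1.00. Of 14242 genes 401 were higher and 517 lower in VWAT. The count was 1417 without VWAT SD 1, 542 without VWAT HFD 1, 511 without VWAT HFD 4, 498 without VWAT HFD 5, 512 without SWAT HFD 4 and 460 without SWAT HFD 5. It was 1544 with 18 libraries and 2214 with the GC correction as well, and 397 genes were higher and 509 lower in all 3 models. With a block of library number within diet it was 272, and 244 of the 918 stayed, though the labels do not pair the libraries.

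Of 31 interferon response genes 23 were lower in VWAT on HFD and 0 higher (28 lower adjusted over the list alone), with a median of -1.31, a camera adjusted p of 5.59e-24 and an adjusted p of 0.127 with an estimated correlation (0.0179 with 18 libraries). The regulator Dhx58 was at -2.38 ± 0.38, Ifit3 at -2.87 ± 0.49, the transcription factor Irf7 at -2.42 ± 0.41 and the antiviral enzyme Oas3 at -5.41 ± 0.98. Inflammatory genes were higher for 7 of 26 and lower for 0 (10 and 1 adjusted over the list alone; camera adjusted p = 5.12e-05, and adjusted p = 0.380 with an estimated correlation), with the eosinophil chemokine Ccl11 at 1.76 ± 0.36, Vcam1 at 1.39 ± 0.29 and Tslp at 1.37 ± 0.31. Genes of DPP4+ interstitial progenitors were lower for 7 of 18 and higher for 0 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00325, and adjusted p = 0.363 with an estimated correlation), with Wnt2 at -2.14 ± 0.44 and Ly6c1 at -1.27 ± 0.27.

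Visceral developmental genes were higher for 4 of 8 (5 adjusted over the list alone) and subcutaneous ones lower for 9 of 16 and higher for 1 (10 and 1 adjusted over the list alone). Their camera adjusted p values were 3.25e-05 and 1.03e-06, and the adjusted p was 0.198 for both with an estimated correlation (0.00216 and 7.56e-04 with 18 libraries). Mural genes were higher for 2 of 13, the contractile genes Mylk at 1.68 ± 0.26 and Myh11 at 1.21 ± 0.33 (6 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00179, and adjusted p = 0.363 with an estimated correlation). The edgeR adjusted p of Myh11, 0.0317 with all 20 libraries, was 0.0810 without VWAT HFD 3, 0.05002 without VWAT HFD 4, 0.0628 without VWAT HFD 5, 0.0682 without SWAT HFD 1, 0.0739 without SWAT HFD 2 and 0.0597 without SWAT HFD 5. Mitosis and DNA replication genes had medians of 0.81 and 0.58 with 0 members past edgeR's threshold (camera adjusted p = 0.00103 and 9.49e-05, and adjusted p = 0.627 and 0.516 with an estimated correlation). Epithelial genes were lower for 3 of 15 (13 adjusted over the list alone; camera adjusted p = 1.55e-08, and adjusted p = 0.363 with an estimated correlation), and lower for 13 with 18 libraries.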

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

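The tests of all 3 patterns weighed here were chosen after the results were seen. So were the lists whose medians were set against other splits, the counts of lists between depots on HFD, all splits of 18 libraries with or without the GC correction, and splits that move the same numbers together. Counts under other splits of all 20 libraries were otherwise planned. A library was singled out when its gap to the nearest other library of its group exceeded 0.71 of the group's range. That held in 42 of 288 groups of 5 libraries, or 14.6%. VWAT SD 5 accounts for 14 of them, SWAT SD 5 for 11, VWAT SD 1 and SWAT SD 4 for 4 each. Chance gives 5% for independent normal values. The genes and lists tested overlap and the same libraries recur, so the 14.6% cannot be held against that 5%.

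The library labelled VWAT SD 5 stood apart from the other VWAT SD libraries, as gap over range, in the scores of interferon response (0.872), visceral developmental (0.899), subcutaneous developmental (0.739), epithelial (0.858) and ovary genes (0.714). It was lowest in Wt1 (0.854) and Tcf21 (0.945) and highest in Irx1 (0.854), Krt8 (0.712), Krt18 (0.838), Epcam (0.774), Csn3 (0.856), Ltf (0.883) and Col1a1 (0.731). The library labelled SWAT SD 5 was the lowest of its group in the epithelial score (0.714), Tbx15 (0.897), Shox2 (0.842), Irx1 (0.972), En1 (0.928), Krt8 (0.744), Krt18 (0.733), Epcam (0.791), Csn3 (0.788) and Fabp4 (0.839), and the highest in Tcf21 (0.712).

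An exchange of these libraries' labels and a mixture of cells of both depots were weighed as explanations. Over genes that differ between depots on HFD by at least 4 on the log2 scale (28 and 63 genes), VWAT SD 5 held 105.6% and SWAT SD 5 84.4% of the other depot's level, and 0.850% and 0.602% of the named depot's. The 0.850% argues against a mixture, and the 84.4% is consistent with an exchange, which may have happened at any step from dissection to deposit. Over all 918 genes called between depots on HFD, VWAT SD 5 lay nearer SWAT on 87.4% and SWAT SD 5 nearer VWAT on 70.6%. The other SWAT SD libraries lay nearer SWAT on 79.7% to 93.5%, and the other VWAT SD libraries nearer VWAT on 63.8% to 86.1%. Both libraries thus lay within the range of the depot that their labels do not name, as an exchange would give. A test that asked for higher shares left the exchange open, since some of the other 8 SD libraries fell short of them too. Of 25 exchanges of a VWAT SD with a SWAT SD library this pair gave 1571 genes between depots on SD. VWAT SD 1 with SWAT SD 3 gave 3905, and these have the lowest and highest GC trend of the SD libraries (-0.54 and 0.62). The count may follow the GC trend as well, so it neither singles the number 5 pair out nor argues against it. No label was changed here.

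Diet fold changes alike in both depots (r = 0.717 across genes) were set against 3 technical explanations. The part of a GC trend that the correction removes is argued against as the whole cause. After GC correction of 18 libraries r stayed at 0.536 (0.456 to 0.565 with 1 more library left out). Genes called in both depots were 10.4 times as many as independent lists share. That reference is low, since other splits that move the same numbers together had a median r of 0.188 after the correction. What set libraries apart beyond the correction, as the splits of VWAT show below, stays open as a part of r. The number 5 libraries are argued against as the cause by r = 0.704 without them (0.617 to 0.733 with 1 more left out). The share of unassigned reads stays open and cannot be fully told apart from diet. With 18 libraries r was 0.519 with it as a covariate, whose slope both depots' fold changes share. The 0.111 among the 14 of them under 6% decides nothing. There the only VWAT SD library left is VWAT SD 1, which has the GC trend of the HFD libraries (-0.54). A shared response of both depots to the diet remains a hypothesis, and the GC correction could also remove biology that follows GC content.

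Expression of Pgr and Greb1 and of the mitosis genes, as deviations from the group means, moved together in the VWAT and SWAT libraries of the same number (9 numbers, without number 5 on SD; 7 measures tested), as did DNA replication (r = 0.931) and other estrogen response genes (r = 0.892; exact two-sided permutation p = 0.0113 adjusted for both), while matrix (r = 0.239), immediate early (r = 0.225) and interferon genes (r = -0.56) did not pass (0.777, 0.691 and 0.239 adjusted). For the mitosis score r was 0.849 and rho 0.933 (exact two-sided permutation p = 0.00104 and 6.94e-04; 0.00729 adjusted for r), 0.839 without the 2 farthest, 0.937 on HFD and 0.925 on SD. For Pgr and Greb1 r was 0.740 and rho 0.750 (exact two-sided permutation p = 0.0372 and 0.0396; 0.0650 adjusted for r), 0.790 without the 2 farthest, 0.975 on HFD and 0.444 on SD, and r did not pass the adjustment. A GC trend is argued against for mitosis by r = 0.865 and for Pgr and Greb1 by 0.738 after GC correction, but stays open for the other estrogen response genes, at 0.279, and epithelial cells by r = -0.82 of Pgr and Greb1 with the epithelial score in SWAT. A candidate explanation is that a number marks mice, or a sort, shared by both depots, so that a pool's estrous stage or cell yield could show in both; estrous stage is not given in the sources used here and was not tested.

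VWAT SD 1 was the lowest of its group in the GC trend (0.905), the lipogenesis score (0.858), the leukocyte score (0.845) and Pdgfrb (0.743). VWAT SD 4 was the highest in Greb1 (0.743). In VWAT HFD, library 3 was the highest in the leukocyte score (0.765) and the macrophage gene Lyz2 (0.837), and library 1 the lowest in the Schwann score (0.889) and the highest in Tcf21 (0.733). SWAT SD 4 was the highest in unassigned reads (0.787) and the lowest in the DNA replication score (0.736), Ccnb1 (0.711) and Adipoq (0.783). In SWAT HFD, library 2 was the highest in the GC trend (0.762) and the lowest in the inflammatory score (0.722), and library 1 was the highest in the endoplasmic reticulum stress score (0.711) and Upk3b (0.793).

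Effects of HFD that differed between depots by the interaction were Frzb with 18 libraries (3.27 on the log2 scale; edgeR adjusted p = 0.0439) and 11 lists by camera, each lost with an estimated correlation (adjusted p from 0.262 to 0.785). The edgeR call of Frzb held only without VWAT SD 1, SWAT SD 3, SWAT SD 4 or VWAT HFD 3 among 18 leave-outs, and was lost in the other 14. Camera adjusted p values were 0.00142 for DNA replication, 1.15e-07 for inflammatory, 1.04e-11 for interferon, 0.0425 for endoplasmic reticulum stress, 0.0208 for DPP4+ progenitor, 0.0162 for visceral developmental, 0.00142 for subcutaneous developmental, 0.0425 for leukocyte, 0.0162 for mural, 0.00215 for epithelial and 0.00142 for ovary genes. Medians of the epithelial, subcutaneous and interferon lists, -3.80, -0.99 and -0.83 with 20 libraries, were 2.0, -0.05 and -0.35 with 18. Table entries that carry a date in place of a symbol, which no comparison used, held 0.157% of reads in VWAT HFD and 0.133% in SWAT HFD, against 0.115% and 0.109% on SD (exact two-sided permutation p = 0.0317 and 0.0159, n = 5; 0.0635 and 0.0444 adjusted over 14 tests).

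Counts were set against other splits of the same libraries into groups of the same sizes. The real grouping is itself among the 100 or 35 splits and counts as reaching its own value, here and for the lists below. For HFD in VWAT 2 of 100 splits gave as many genes as the real 6502, highest other 7524, and with 18 libraries 2 of 100 (5247, highest other 7000) and after GC correction 2 of 100 (1996, highest other 2094), so chance can be excluded at 0.05. For SWAT the splits were 2 of 100 (222, highest other 1676), 2 of 100 (92, highest other 853) and 1 of 100 (229, highest other 1), which also excludes chance. With 20 and with 18 libraries the highest split in both depots exchanged SD 1 with HFD 2, which groups the libraries by their GC trend. In VWAT this exchange was still the highest after GC correction, so the correction did not remove what sets these libraries apart, while in SWAT another split was. With 20 and with 18 libraries it called several times the real count in SWAT, which points to a structure of the samples. For the interaction and between depots on SD every split of 20 libraries reaches a real count of 0 genes (100 of 100 each; highest other 3899 and 4515), so these splits say nothing about chance. For the interaction 2 of 100 splits reached the 1 gene of 18 libraries (highest other 1553), again a structure of the samples. Between depots on SD chance cannot be excluded for the 1214 of 18 libraries (5 of 35; highest other 4880, several times the real count, a structure of the samples), while 1 of 35 reached the 1789 after GC correction (highest other 1438), a share that does not allow for the choice of the 18 libraries by their depot genes. On HFD 1 of 100 splits reached 918 (highest other 0), 1544 (highest other 0) and 2214 (highest other 43), so chance can be excluded. For the agreement of the depots 1 of 100 splits that move each depot on its own reached 0.717 (highest other 0.656) and 1 of 100 reached 0.704 with 18 libraries (highest other 0.561). Of splits that move libraries of the same number together, 2 of 100 reached 0.717 (highest other 0.719). With 18 libraries 4 of 100 reached 0.704 (highest other 0.754), and 4 of 100 reached 0.536 after GC correction (highest other 0.574). Splits of this kind were chosen after the results and 100 of 126 possible ones were run, so their shares do not exclude chance. The highest of these with 20 and with 18 libraries again exchanged SD 1 with HFD 2.

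Numbers of lists called by camera were reached by chance: 77 of 100 splits for the 6 in VWAT (highest other 17), 96 for the 5 in SWAT (17), 30 for the 11 of the interaction (20), 11 for the 12 on SD (16) and 29 for the 13 on HFD (19), so chance cannot be excluded for any of these counts. Medians of single lists differed in how often splits reached them. The mitosis medians of 2.75 in VWAT and 2.74 in SWAT were reached in 1 of 100 splits each (highest other 2.54 and 2.48). The matrix medians of 0.58 and 0.51 were reached in 1 each (highest other 0.516 and 0.395). The interferon median of 0.91 in SWAT was reached in 2 (highest other 0.934). That of -1.31 between depots on HFD was reached in 1 (highest other 1.02). These shares do not allow for the choice of lists after the results, so they do not exclude chance for a chosen list. With 20 libraries the subcutaneous developmental median of -1.07 in VWAT was also reached in 1 of 100 (highest other 1.04). With 18 libraries 44 of 100 reached that list's median. Mitosis and matrix medians of both depots stayed at 1 of 100 with 18 libraries, with or without the GC correction. With 18 libraries the interferon median of 0.60 in VWAT was reached in 1 of 100 (highest other 0.46) and that of 0.67 in SWAT in 3 (highest other 0.816). Chance cannot be excluded for oxidative phosphorylation in SWAT (33 of 100), or on HFD for mitosis (16), DNA replication (13), endoplasmic reticulum stress (10) and leukocyte genes (8). After GC correction of 18 libraries it cannot be excluded either for DNA replication in VWAT (22 of 100) and SWAT (20), or in VWAT for leukocyte (8) and inflammatory genes (5). Nor can it for the interaction medians of the called lists, reached in 11 (interferon) to 78 (epithelial) of 100 apart from ovary genes (4). With 18 libraries 49 reached the interaction median of interferon, 42 that of ovary (0.44) and 4 that of epithelial genes, which had changed sign. On SD with 20 libraries the called lists were reached in 6 (muscle) to 62 (mitosis) of 100, apart from cholesterol and mesothelial genes (3 each). With 18 libraries on SD they were reached in 1 of 35, apart from visceral developmental (3) and endothelial, estrogen response and glycolysis genes (7 each), again without allowing for the choice of libraries.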

How the results depend on the processing

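Every alternative computed from 18 libraries, the GC correction, the unassigned share as a covariate and the restriction to libraries under 6% unassigned were chosen after seeing the data, and so were list tests between depots on HFD. The others were fixed before the data were examined. For each value below that moved, the cause was not tested, except that fewer libraries or genes enter some alternatives by construction. A sign change of a gene past the threshold in neither setting was not counted as a reversal. Single genes gave 755 results and 20535 values, of which 10 reversed. Cd34 in VWAT, at 0.10 with all 20 libraries, was at -0.81 with the GC correction (edgeR adjusted p = 0.0244) and at -0.77 with 18 libraries and the GC correction (edgeR adjusted p = 0.0441). The clock gene Per1 in VWAT, which fell with all 20 libraries, was at 0.20 with the GC correction and 0.28 with 18 libraries and the GC correction. Krt8 and the mural gene Kcnj8, which also fell in VWAT, ranged from -5.44 (without VWAT SD 2) to 0.0756 (without VWAT SD 5) and from -3.41 (without VWAT SD 4) to 0.21 (without VWAT SD 5). They were at 0.0776 and 0.21 with 18 libraries, and at 1.00 and 0.63 with 18 libraries and the GC correction. Leaving out 1 library kept 13771 of these values on their side of the threshold, lost 723 and gained 224. DESeq2's size factors kept 749, lost 5 and gained 1. No alternative changed the depth of the libraries, and genes near 1 CPM and the lists of muscle, ovary and erythroid genes rest on few reads.

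Genes called for HFD in VWAT numbered 6502, and 2422 with the GC correction, 1996 with 18 libraries and the GC correction, 1880 with the unassigned share as a covariate and 3171 at a log2 fold change of at least 1. They stayed within 1.5 times under DESeq2's size factors (6477), upper quartile scaling (6492), DESeq2 (7086), limma-voom (9074), no filter (5419), the stricter filter (6401), the 10 libraries alone (5098) and 18 libraries (5247). limma-voom moved the share of higher calls from 43.1% to 50.8%.

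In SWAT the 222 genes became 2003 with DESeq2, 3713 with limma-voom, 44 without a filter, 1939 with the 10 libraries alone, 92 with 18 libraries, 99 with the GC correction and 0 with edgeR and the unassigned share as a covariate. The share of higher calls, 55.0%, was 81.8% with the GC correction and 63.6% without a filter, but under 50% with upper quartile scaling (47.1%), DESeq2 (47.5%), the stricter filter (48.1%), the 10 libraries alone (48.3%) and limma-voom (49.3%). The interaction, 0 by edgeR (605 at an unadjusted p under 0.05) and by DESeq2, gave 2220 with limma-voom, 1 with 18 libraries and 1 with the GC correction as well. VWAT against SWAT on SD, 0 by edgeR (1009 at an unadjusted p under 0.05), gave 15 with DESeq2, 1318 with limma-voom, 1214 with 18 libraries and 1789 with the GC correction as well. On HFD the 918 genes became 1468 with DESeq2, 5300 with limma-voom, 2767 with the 10 libraries alone, 1544 with 18 libraries, 1435 with the GC correction and 2214 with both. The correlation of the depots' fold changes, 0.717, was 0.281 without a filter, 0.812 with the stricter filter, 0.538 with the GC correction, 0.536 with 18 libraries and the GC correction, and 0.644 with the covariate.

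With 18 libraries the VWAT count, 5247, was 9117 with limma-voom, 1996 with the GC correction, 18 with the covariate and 1 in libraries under 6% unassigned. The SWAT count, 92, was 57 with DESeq2's size factors, 1626 with DESeq2, 4164 with limma-voom, 229 with the GC correction, 0 with edgeR and the covariate, and 372 in libraries under 6%. The interaction, 1, was 0 by edgeR with DESeq2's size factors, with the covariate and in libraries under 6% (438 at an unadjusted p under 0.05 with 18 libraries), and 3506 with limma-voom. On SD 1214 became 4273 with limma-voom, and on HFD 1544 became 5186. The correlation, 0.704, was 0.536 with the GC correction, 0.519 with the covariate and 0.111 in the 14 of them under 6%, where VWAT SD 1 is the only VWAT SD library left.

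Lists called by camera, 6 for VWAT, 5 for SWAT, 11 for the interaction, 12 on SD and 13 on HFD, were 0 for each with an estimated correlation. The SWAT lists were 3 with the stricter filter, 11 with 18 libraries, 10 with the GC correction as well, 9 with the covariate and 3 with fry. fry called 0 lists for the interaction and 0 on SD. With 18 libraries the lists, 7, 11, 8, 11 and 12 in the same order, were 0, 0, 0, 4 and 5 with an estimated correlation, and fry called 4 for VWAT, 6 for SWAT and 0 for the interaction.

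Replicate numbers were not treated as pairs, since the labels do not say so and not every pair exceeded a correlation of 0.1, though scores of mitosis, DNA replication and estrogen response genes moved together by number between depots (exact two-sided permutation p = 0.00729, 0.0113 and 0.0113, adjusted over 7 measures). For estrogen response genes r fell to 0.279 after GC correction. The correlation of deviations exceeded 0.1 in 3 of 5 pairs for VWAT SD with VWAT HFD (-0.213 to 0.371), 2 for SWAT SD with SWAT HFD (-0.306 to 0.259), 1 for VWAT SD with SWAT SD (-0.657 to 0.594) and 4 for VWAT HFD with SWAT HFD (0.0922 to 0.547). Of 5 libraries, the best match had the same number for 2, 2, 1 and 2 of them in these pairings. The -0.657 between depots on SD is that of number 5, whose libraries carry the other depot's genes, so it cannot speak against pairing. Deviations on SD were taken from group means that include both of these libraries, which also enters the values of the other SD pairs. With the replicate number as a block, 6865 genes were called in VWAT, 2088 in SWAT (1120 with 18 libraries) and 906 between depots on HFD, where a block of number within diet gave 272. The correlation was 0.760 with the block.

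Leaving out 1 library at a time gave 4432 (without VWAT SD 2) to 8505 (without VWAT SD 1) genes in VWAT, 0 (without SWAT SD 2, among others) to 3362 (without VWAT SD 1) in SWAT, 0 to 0 for the interaction, 0 to 590 (without VWAT SD 5) on SD and 460 (without SWAT HFD 5) to 1417 (without VWAT SD 1) on HFD. The correlation ranged from 0.624 (without SWAT SD 3) to 0.757 (without SWAT SD 5). The lists ranged from 4 to 7, 3 to 8, 8 to 12, 9 to 14 and 12 to 16. With 18 libraries the ranges were 1866 (without VWAT SD 2) to 8394 (without VWAT SD 1), with 2567, 1995 and 3356 without VWAT SD 3, VWAT SD 4 and VWAT HFD 5, then 0 to 3315 in SWAT, 0 to 1 for the interaction, 964 to 1821 on SD, 1212 to 2059 on HFD and 0.617 to 0.733 for the correlation.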

Other observations

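Several further lists had members that moved with HFD in VWAT without a call of the list. Of 18 glycolysis genes 2 rose and 11 fell (2 and 12 adjusted over the list alone; camera adjusted p = 0.0946), with a median of -0.71, and -0.10 with 18 libraries and the GC correction. Of 47 oxidative phosphorylation genes 5 rose and 16 fell (5 and 15; camera adjusted p = 0.0946). Hexokinase 1, Hk1, fell by 0.86 and the pyruvate kinase Pkm2 by 0.96 on the log2 scale. Cholesterol genes went both ways, 8 of 23 rising and 6 falling (8 and 6 adjusted over the list alone). The synthesis enzymes Cyp51 and Idi1 rose by 1.28 ± 0.26 and 1.66 ± 0.38. Endoplasmic reticulum stress genes rose for 8 of 25 and fell for 2 (8 and 2 adjusted over the list alone), with the chaperone Hsp90b1 at 1.27 ± 0.32. Immediate early genes rose for 3 of 25 and fell for 10 (4 and 11 adjusted over the list alone), among them Ier2 by 1.88 and Junb by 1.17, genes that cell isolation is known to induce. The immediate early median was -0.59, and 0.20 with 18 libraries and the GC correction, where 2 rose and 0 fell (2 and 0 adjusted over the list alone). Of 17 clock genes 2 rose and 5 fell (2 and 5 adjusted over the list alone), with the output factors Dbp and Tef down by 1.48 and 1.24. DPP4+ progenitor genes fell for 6 of 18 and rose for 1 (6 and 1 adjusted over the list alone), with Dact2 down by 2.37 ± 0.35 (edgeR adjusted p = 0.00138) and Pi16, a surface marker of these progenitors, down by 1.56 ± 0.28 (edgeR adjusted p = 0.00302). Liver X receptor targets rose for 2 of 11 and fell for 6, fatty acid oxidation genes rose for 1 of 24 and fell for 4, glucocorticoid targets rose for 1 of 17 and fell for 5, and CD142+ genes rose for 3 of 10 and fell for 1. Adjusted over the list alone these were 2 and 6, 1 and 4, 1 and 1, and 3 and 1. Interferon genes rose for 4 of 31 and fell for 6 in VWAT (4 and 5 adjusted over the list alone; camera adjusted p = 0.881), with a median of -0.18. With 18 libraries 9 rose and 4 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.186), with a median of 0.60, and the median was 0.26 with the GC correction as well.

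Among genes of other cell types, 0 of 18 endothelial genes rose and 5 fell in VWAT, 0 of 14 mesothelial genes rose and 5 fell, 1 of 13 mural genes rose and 1 fell, 2 of 11 Schwann genes rose and 2 fell, and 1 of 7 ovary genes and 1 of 8 visceral developmental genes rose. Adjusted over the list alone, 0 endothelial and 5 mesothelial genes fell, 1 mural gene rose and 1 fell, 2 Schwann genes rose and 2 fell, and 1 ovary and 0 visceral genes rose. 0 of 16 subcutaneous developmental genes rose and 7 fell (0 and 7 adjusted over the list alone; 0 and 3 with 18 libraries), and 0 of 15 epithelial genes rose and 13 fell (0 and 13 adjusted over the list alone), where 2 rose and 1 fell with 18 libraries. 0 muscle and 0 erythroid genes passed edgeR's threshold in VWAT or SWAT. Between depots, mesothelial genes went both ways. With 18 libraries on SD 8 of 15 were higher in VWAT and 5 lower (8 and 6 adjusted over the list alone; camera adjusted p = 0.275), with uroplakin 3b, Upk3b, at 6.46 ± 0.75 (SE; edgeR's test). On HFD 5 of 7 ovary and reproductive tract genes were higher in VWAT (5 adjusted over the list alone; camera adjusted p = 3.96e-04, and adjusted p = 0.127 with an estimated correlation), with Star, which brings cholesterol to steroid synthesis, at 3.16 ± 0.58. Schwann genes were lower in VWAT on SD for 2 of 11, Mbp at -2.18 ± 0.24 and Sox10 at -4.02 ± 0.85 (camera adjusted p = 0.0432, and adjusted p = 0.0905 with an estimated correlation), and muscle genes for 2 of 7 (camera adjusted p = 0.0491, and adjusted p = 0.233 with an estimated correlation). Endothelial and glycolysis lists lay higher in VWAT on SD by camera (adjusted p = 0.0241 and 0.0491, and adjusted p = 0.684 and 0.715 with an estimated correlation). On HFD leukocyte genes lay lower and endoplasmic reticulum stress genes higher in VWAT as lists (camera adjusted p = 0.0235 and 0.0207, and adjusted p = 0.627 and 0.542 with an estimated correlation), with 0 genes of either past edgeR's threshold. Cholesterol genes had 1 of 23 lower on HFD, Sc4mol at -1.19 ± 0.23 (camera adjusted p = 0.00291, and adjusted p = 0.516 with an estimated correlation).

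Some measures of RNA content differed between the diets. Mitochondrial transcripts were 0.898% ± 0.195 of reads in VWAT HFD and 0.457% ± 0.155 in VWAT SD (exact two-sided permutation p = 0.00794, 0.0444 adjusted over 14 tests; n = 5), and 0.661% and 0.482% in SWAT (p = 0.0635, adjusted 0.111, by the same exact test). Transcripts of ribosomal proteins were 1.82% ± 0.174 in SWAT HFD and 2.71% ± 0.83 in SWAT SD (exact two-sided permutation p = 0.00794, 0.0444 adjusted), and 2.13% and 2.74% in VWAT (exact p = 0.111, adjusted 0.139). Reads that aligned to more than 1 place were 17.2% and 20.8% in SWAT HFD and SD (exact p = 0.0159, adjusted 0.0444), and 19.96% and 22.4% in VWAT (exact p = 0.0952, adjusted 0.133).

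A hypothesis chosen after the results were seen was that pools with more Pgr and Greb1 mRNA hold more dividing cells. Over 18 libraries, deviations of Pgr and Greb1 from their group means had r = 0.484 and rho = 0.534 with those of the mitosis score (two-sided permutation p = 0.068 and 0.0413; 0.136 adjusted over 6 measures for r), 0.420 without the 2 farthest libraries and 0.503 after GC correction. Within VWAT r was 0.260 and within SWAT 0.761. For the DNA replication score r was 0.523 (two-sided permutation p = 0.035, 0.128 adjusted), 0.440 within VWAT and 0.662 within SWAT. For the epithelial score it was -0.56 (two-sided permutation p = 0.043, 0.128 adjusted). None of the 6 measures passed the adjustment. The permutation p of r for the mitosis score missed 0.05, so the test did not bear the hypothesis out, and a relation cannot be excluded with 18 libraries.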
